A study of Mus musculus with 12 samples.

How the data were processed

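Isolated pancreatic islets of 12 male mice aged 11 weeks were profiled by RNA sequencing, 1 library per mouse and 3 mice in each of 4 groups. The groups cross the NOD/LtJ background (NOD) or the C57BL/10 background (B10) with the absence or presence of insHEL, a transgene that places hen egg lysozyme under an insulin promoter (NOD_insHEL and B10_insHEL). Per the labels, all mice lack a Rag gene, carry the MHC k haplotype and were normoglycemic. Per the labels' protocols, pancreata were digested with collagenase in the presence of the transcription inhibitors α-amanitin and actinomycin D, islets were enriched on a dextran gradient and picked under a microscope, and libraries were made with a stranded mRNA kit. The number of picked islets per library ranged from 20 to 137.

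The deposited file holds raw read counts per Ensembl gene, 1 column per library, for 38561 genes. Per the submitters' processing notes, reads were mapped to GRCm38 and the tools named are cutadapt, TopHat2 2.0.8b, HTSeq and DESeq. The annotation release, the strand setting and the counting mode are not stated. Whole numbers from 0 and column totals that differ between libraries were checked and fit raw counts. All columns were used. Gene symbols, coordinates and gene types were added by Ensembl identifier from GENCODE vM21 on GRCm38: 36639 identifiers (95.0%) have a symbol there, and they hold 99.8% of the counts. The file has no entry for the insHEL construct, so the transgene itself was not measured.

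Library totals were 16320983, 21138456 and 13920858 counts for B10 replicates 1 to 3, 9904849, 11479112 and 10493508 for B10_insHEL, 11874188, 13240553 and 6765595 for NOD, and 10841939, 7784092 and 2212062 for NOD_insHEL. A gene with 0 counts in a library can therefore have been present at up to 0.142 CPM (counts scaled to a common library total, here 3 counts in the deepest library) to 1.36 CPM (3 counts in the shallowest). Intervals on shares are exact 95% binomial intervals. Where all libraries of one side have 0 counts, a fold is a lower bound computed against 3 counts summed over the libraries of that side, and with 1 to 3 counts it is a ratio of pooled CPM with its exact 95% counting interval. Reads carry no molecular identifiers, so that intervals and floors cover counting error only.

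Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr with the 4 groups were kept (15352), library sizes were scaled by TMM, and 1 model with the 4 group means was fitted to all 12 libraries with robust quasi-likelihood dispersions (common biological coefficient of variation 0.142). Tests are edgeR's quasi-likelihood F-tests, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The 6 comparisons are NOD_insHEL against B10_insHEL, NOD against B10, the strain difference averaged over the transgene (6 libraries against 6), B10_insHEL against B10, NOD_insHEL against NOD, and the interaction, which is the transgene effect in NOD minus that in B10. Standard errors are the absolute log2 fold change divided by the square root of F. Expression is given as TMM-scaled CPM, mean ± SD over 3 mice. The lower bounds of folds, the pooled ratios and the acinar score also use TMM-scaled CPM. Only the CPM that 0 counts in a single library allow use the unscaled library total.

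The sample descriptions number the 3 B10 libraries 101, 102 and 104 and the other 9 libraries from 1 to 29. If these numbers mark a preparation batch, it holds libraries of 1 group only, so that batch and group cannot be told apart in any comparison that uses B10. The comparisons of NOD_insHEL with B10_insHEL and of NOD_insHEL with NOD lie within the numbers 1 to 29, and the former is given beside most strain differences averaged over the transgene.

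A total of 27 gene lists with 523 symbols (516 in the file) were tested with camera in limma 3.58.1 at the preset correlation of 0.01, Benjamini-Hochberg adjusted over the 27 lists within a comparison. Of 162 list tests 40 passed. With a correlation estimated from the data 0 of the 162 passed, the lowest adjusted p being 0.200, while 15 of the 40 also passed fry, which asks whether the genes of a list move one way without comparing them with other genes. Member counts are given over all genes tested and adjusted over the list alone.

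Genes were named by a rule. For the averaged strain difference and the transgene in each strain, the rule takes the 10 genes with the highest and the 10 with the lowest log2 fold change among genes with an adjusted p under 0.05, a mean of at least 1 CPM on one side and no overlap between the libraries of the 2 sides. Without any difference, 10% of genes would show no overlap between 3 and 3 libraries. Predicted and unnamed genes were left out, 198 of 1704 for the averaged strain difference, 55 of 1026 for the transgene in B10 and 69 of 1041 for the transgene in NOD. For the strain difference within transgenic or non-transgenic islets, the same genes and the 3 next highest and 3 next lowest were taken. The interaction adds the 5 genes with the smallest p, each list adds up to 4 members in order of p, and Ins1, Ins2, Gcg, Sst, Ppy, Glis3, Xrcc4, Manf, Hspa5, Prss2 and Ptprc are included everywhere. The comparisons, lists, this rule and the first set of alternatives were chosen before the data were examined.

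The alternatives were RLE scaling, TMM without acinar, red blood cell and mitochondrially encoded genes, no filter on low counts, a stricter filter (5 CPM in 3 libraries), the Wald test of DESeq2 1.42.0, dispersions without robust estimation, a fit of only the groups compared, the replicate number as a block, the log2 number of picked islets or the acinar score as a covariate, and leaving out each library in turn. The acinar score is the mean log2 CPM of the acinar list in a library. Within groups it varied mainly through B10_insHEL replicate 2, so that results with this covariate rest largely on that library. Added after the data were seen were leaving out both B10_insHEL replicate 2 and NOD_insHEL replicate 3, and thinning every library at random to 2212062 counts. Where 1 library of a group was left out, the other 2 and the remaining groups supplied the spread. Other groupings of the same libraries were fitted in the same way, all 10 for 3 against 3 and 100 drawn at random for the averaged strain difference and the interaction.

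The procedure was tested on simulated counts with the depths of these libraries and 200 changed genes per comparison. Of genes changed 2-fold, 49.3% were recovered for strain in transgenic islets, 79.1% for strain in non-transgenic islets, 79.1% for strain averaged, 74.6% for the transgene in B10, 67.2% for the transgene in NOD and 41.8% for the interaction. At 4-fold the recovery was 81.8 to 93.9% for the comparisons of groups and 78.8% for the interaction, and at 1.5-fold it was 22.4 to 53.7% and 2.99%. False calls made up 8 of 144 calls for the transgene in NOD, the lowest share of the 6 comparisons. The highest share was 21 of 197, for strain averaged. None of the recovered genes had the wrong sign, and 0 or 1 of 26 unchanged lists was called in each comparison. The unchanged lists held random genes simulated independently of each other. They therefore cannot show how often lists of correlated genes are called falsely.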

Results

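Islet transcriptomes of NOD/LtJ and C57BL/10 (B10) mice were compared in mice that lack a Rag gene, which mature B and T cells need. Insulin transcripts took a large part of every library. Ins1 and Ins2 together held 15.8% of counts in B10 replicate 2 (exact 95% binomial interval 15.7 to 15.8%), the lowest of the 12 libraries. The highest share was 25.6% in NOD_insHEL replicate 3 (25.5 to 25.6%). Rag2 had 0 counts in all 12, while Rag1 had 13 to 141. Ptprc, which encodes the pan-leukocyte marker CD45, had 8.99 ± 1.06 CPM (mean ± SD, n = 3) in B10 and 11.5 ± 3.03 CPM (n = 3) in NOD, and its strain difference averaged over the transgene missed the threshold (log2 difference 0.39, SE 0.18, adjusted p = 0.0997, and 0.42 with adjusted p = 0.324 within transgenic islets). Of the lymphocyte list 3 of 20 genes were measurable, and the list was not called for strain (median log2 difference 0.42, adjusted p = 0.755). The first principal component of the log2 CPM (43.0% of the variance) set the 6 NOD libraries (31.2 to 54.8) apart from the 6 B10 libraries (-47.8 to -31.3), and the second (14.9%) set the 6 insHEL libraries (-35.5 to -6.86) apart from the 6 without it (18.9 to 25.2).

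Islets of the 2 backgrounds differed widely. Averaged over the transgene, 5107 of 15352 genes passed the threshold, 2406 higher and 2701 lower in NOD, of which 583 and 523 differed at least 2-fold. Within the libraries numbered 1 to 29 (NOD_insHEL against B10_insHEL) 1850 genes passed, 852 higher and 998 lower. NOD against B10 gave 4353, 2065 higher and 2288 lower, and 2868 without NOD replicate 3. Both strain comparisons shared 592 genes higher in NOD (114.6 expected by chance) and 751 lower (148.7 expected), with 6 called in opposite directions. The counts with the acinar score as a covariate were 2090 for the averaged difference and 1111 for NOD against B10. With each library thinned to the depth of the shallowest they were 1079 averaged, 260 for NOD_insHEL against B10_insHEL and 692 for NOD against B10.

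Acinar enzymes, the digestive enzymes of the exocrine pancreas, separated the 3 B10 libraries from most others. The acinar score was 5.33 to 5.61 in B10, 2.17 to 2.67 in NOD and 1.32 to 1.81 in NOD_insHEL, while in B10_insHEL it was 1.505 and 1.17 in replicates 1 and 3 and 4.91 in replicate 2. Averaged over the transgene, 25 of 27 measured acinar genes were lower in NOD and 2 did not pass (26 lower when adjusted over the list alone), with a median log2 difference of -4.19 (camera, adjusted p = 0.00104, and 0.895 with an estimated correlation). Without B10_insHEL replicate 2 this median was -1.88. In transgenic islets alone the list did not pass (median -3.79, adjusted p = 0.0905), and without B10_insHEL replicate 2 its direction reversed (median 0.41, adjusted p = 0.0460). Trypsinogen Prss2 had 312 ± 32.4 CPM in B10, 73.0 ± 121 in B10_insHEL, 12.8 ± 5.62 in NOD and 5.34 ± 2.42 in NOD_insHEL (n = 3 each, log2 difference -4.20, SE 1.11, adjusted p = 0.0203, and -3.79 with adjusted p = 0.201 within transgenic islets). Its call ended without NOD_insHEL replicate 1 or 2 (adjusted p up to 0.0552), and its difference was -1.88 without B10_insHEL replicate 2. With the acinar score, which contains Prss2, as a covariate the difference was 0.54 (adjusted p = 0.124). The islet regeneration gene Reg2 moved with the acinar score, with 107 to 172 CPM in the 3 B10 libraries, 85.1 in B10_insHEL replicate 2 and 0.192 to 1.72 in the other 8 (averaged log2 difference -6.96, SE 1.40, adjusted p = 0.00559). Within transgenic islets Reg2 did not pass (-6.38, adjusted p = 0.126). Reads of the Reg3 paralogs can be shared between family members, so that Reg3a, Reg3b and Reg3g are less certain individually.

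**Figure D1:**
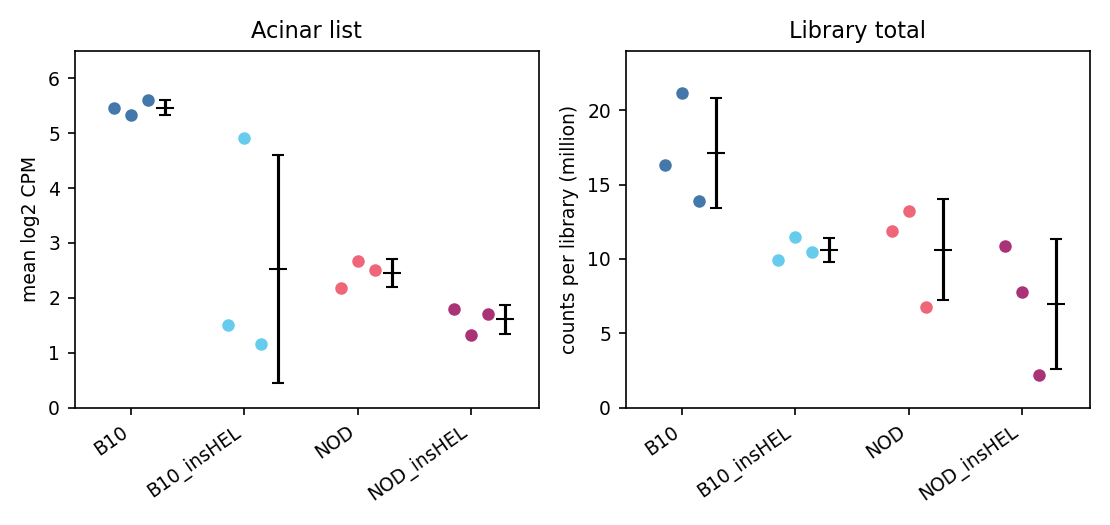
Left, acinar score of each library (mean log2 CPM of the acinar list), and right, library total, points being libraries and bars the mean ± SD of 3. The 3 B10 libraries and B10_insHEL replicate 2 lie between 4.91 and 5.61, the other 8 between 1.17 and 2.67.

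Genes of the integrated stress response were lower in NOD islets. Of 24 measured members of the integrated stress response list 16 were lower, 0 were higher and 8 did not pass (18 lower when adjusted over the list alone), with a median log2 difference of -0.67 (camera, adjusted p = 2.28e-09, and 0.733 with an estimated correlation). Phgdh (ENSMUSG00000053398, chromosome 3, 98313170 to 98339990), which encodes the first enzyme of serine synthesis, had 6.38 ± 1.40 CPM in B10, 7.81 ± 2.84 in B10_insHEL, 0.410 ± 0.150 in NOD and 0.612 ± 0.164 in NOD_insHEL (n = 3 each), a log2 difference of -3.73 (SE 0.28, adjusted p = 2.00e-09). Psat1, the next enzyme of that pathway, differed by -2.15 (SE 0.18, adjusted p = 3.20e-08). Asparagine synthetase Asns (ENSMUSG00000029752, chromosome 6, 7675169 to 7693254) had 190 ± 14.9 CPM in B10 and 64.6 ± 13.6 in NOD (n = 3), with an averaged log2 difference of -1.37 (SE 0.13, adjusted p = 9.44e-07, and -1.18 with adjusted p = 4.17e-04 within transgenic islets). The translation repressor Eif4ebp1 differed by -1.86 (SE 0.21, adjusted p = 1.49e-06). The stress-induced regulator Nupr1 (ENSMUSG00000030717, chromosome 7, 126623249 to 126630861) fell from 126 ± 7.11 CPM in B10 to 9.51 ± 1.13 in NOD (n = 3, log2 difference -3.72, SE 0.35, adjusted p = 5.03e-05). These calls remained when each library was left out in turn, and thinning ended that of Phgdh (-2.69, adjusted p = 0.0885). Within the libraries numbered 1 to 29 the list had a median of -0.59 (10 of 24 lower, 14 adjusted over the list alone, adjusted p = 5.13e-09, and 0.690 with an estimated correlation), Phgdh differed by -3.57 (SE 0.40, adjusted p = 2.46e-06), Psat1 by -2.16 (SE 0.26, adjusted p = 1.09e-05), Eif4ebp1 by -2.13 (SE 0.31, adjusted p = 1.05e-04) and Nupr1 by -3.56 (SE 0.37, adjusted p = 1.78e-04).

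**Figure D2:**
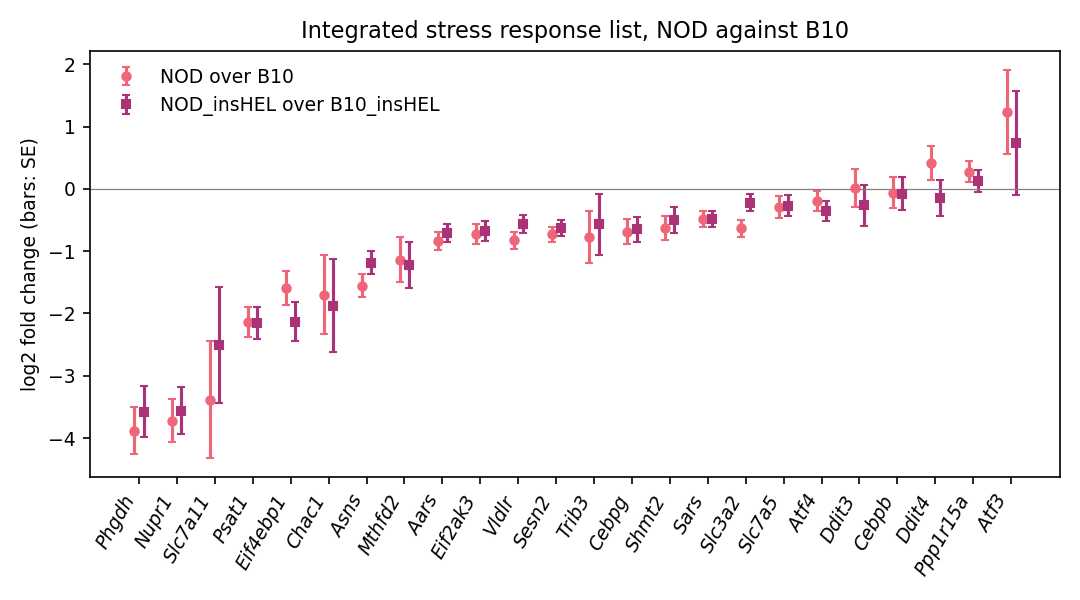
Log2 difference of each measured gene of the integrated stress response list, NOD over B10 (circles) and NOD_insHEL over B10_insHEL (squares), bars giving the SE. The list medians are -0.73 and -0.59, and Phgdh and Nupr1 lie between -3.88 and -3.56 in both comparisons.

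Part of the strain difference in counts was near on or off. Whether reads from NOD alleles of these genes were lost in mapping to GRCm38 was not tested. Counts near 0 in NOD libraries are therefore not shown to be absent expression. Pianp (ENSMUSG00000030329, chromosome 6, 124996694 to 125003096) had 0.653 ± 0.154 CPM in B10, 0.724 ± 0.459 in B10_insHEL, 70.9 ± 7.38 in NOD and 65.1 ± 3.43 in NOD_insHEL (n = 3 each), a log2 difference of 6.56 (SE 0.16, adjusted p = 2.69e-17) and 6.41 within transgenic islets. Tex15 was 6.72 higher (SE 0.24, adjusted p = 1.55e-14), with a ratio of 231 within transgenic islets (3 counts in B10_insHEL, counting interval 78.4 to 1123), and the neuronal gene Klhl1, with 0 counts in all 6 libraries of B10 background, was at least 134-fold higher and at least 88.8-fold within transgenic islets (averaged, adjusted p = 0.0565 with the acinar score as a covariate). Ifi202b, an interferon-inducible gene, was at least 77.6-fold higher in NOD and Trim12a at least 76.9-fold lower, with bounds of 24.2 and 26.4 within transgenic islets. The zinc finger gene Zfp990 was 8.58 higher (SE 0.26, adjusted p = 8.86e-15, and 8.29 within transgenic islets), but it belongs to a cluster of close paralogs, so that the assignment of its reads is uncertain. The ghrelin gene Ghrl had 8.13 ± 5.52 CPM in B10 and 5.57 ± 2.29 in B10_insHEL against 0.127 ± 0.0485 in NOD (n = 3 each, averaged log2 difference -6.23, SE 0.57, adjusted p = 3.21e-07), and within transgenic islets, with 1 count in NOD_insHEL, the ratio was 114 (counting interval 20.1 to 4513). The extracellular matrix gene Cthrc1 differed by -5.26 (SE 0.29, adjusted p = 2.14e-11) and by -6.15 within transgenic islets. All 20 genes named for this comparison kept their call when each library was left out. Among genes with a log2 difference of at least 4 in size, 14.9% were annotated pseudogenes, against 5.69% of the 15352 tested genes (Fisher's exact test, two-sided, odds ratio 2.93, p = 5.65e-04), while among all 5107 called genes the share was 3.92% (odds ratio 0.580, p = 6.44e-12).

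Among hormone and beta cell genes the strain differences went both ways. Of 27 measured beta cell genes 8 were higher and 9 lower in NOD with 10 not passing, and the list was not called (median log2 difference 0.03, adjusted p = 0.755). Iapp, which encodes islet amyloid polypeptide, had 27723 ± 1861 CPM in B10, 36345 ± 1475 in B10_insHEL, 18841 ± 1730 in NOD and 23292 ± 1537 in NOD_insHEL (n = 3 each, log2 difference -0.60, SE 0.08, adjusted p = 1.12e-05). Within transgenic islets Iapp differed by -0.64 (SE 0.12, adjusted p = 6.67e-04). Sytl4, which encodes the insulin granule protein granuphilin, was higher by 0.72 (SE 0.08, adjusted p = 3.24e-07), and by 0.92 within transgenic islets. The cation channel gene Trpm5 was higher by 1.57 (SE 0.19, adjusted p = 1.42e-04), and by 1.80 within transgenic islets. Ins1 had 43867 ± 839 CPM in B10 and 73777 ± 2271 in NOD (n = 3), and the averaged difference was 0.53 (SE 0.10, adjusted p = 4.45e-04). Within transgenic islets Ins1 missed the threshold (0.30, adjusted p = 0.186), as it did with the acinar score as a covariate (0.22, adjusted p = 0.284). Ins2 was higher by 0.34 (SE 0.10, adjusted p = 0.00867), missed the threshold within transgenic islets (0.22, adjusted p = 0.322) and also lost its call with that covariate (0.14, adjusted p = 0.535). Gcg, which encodes glucagon, did not pass (-0.22, adjusted p = 0.741), and neither did Ppy (-0.67, adjusted p = 0.214). Among alpha cell genes Gc was lower (-0.99, SE 0.09, adjusted p = 4.92e-08, and -1.07 within transgenic islets). Somatostatin (Sst) was higher by 0.86 (SE 0.24, adjusted p = 0.0228, and 0.97 with adjusted p = 0.109 within transgenic islets), a call lost without B10_insHEL replicate 2, NOD replicate 3, NOD_insHEL replicate 1 or NOD_insHEL replicate 3 (adjusted p up to 0.0554) and with the acinar score as a covariate (adjusted p = 0.401).

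Glis3, a beta cell transcription factor gene, and the DNA repair gene Xrcc4 were examined in every comparison. Glis3 had 68.8 ± 4.01 CPM in B10, 78.0 ± 11.5 in B10_insHEL, 57.5 ± 5.54 in NOD and 61.4 ± 12.5 in NOD_insHEL (n = 3 each). Its averaged log2 difference of -0.29 (SE 0.10) passed at an adjusted p of 0.0243, but neither strain comparison passed alone (adjusted p = 0.139 in transgenic and 0.155 in non-transgenic islets). The call ended without B10_insHEL replicate 2, NOD replicate 3 or NOD_insHEL replicate 3 (adjusted p up to 0.0701), with the islet number as a covariate (0.0665) and with the acinar score as a covariate (0.615). Xrcc4 did not pass (-0.11, SE 0.12, adjusted p = 0.522, and 0.993 within transgenic islets). Of the double-strand break repair list, which includes Xrcc4, 4 of 20 genes were lower and the list was not called (median -0.07, adjusted p = 0.293). Xrcc6, which encodes the Ku70 subunit, had 45.4 ± 2.67 CPM in B10 and 21.5 ± 2.37 in NOD (n = 3, averaged log2 difference -0.999, SE 0.09, adjusted p = 6.93e-08, and -0.92 within transgenic islets). Cdkn1a, a p53 target, was lower (-1.14, SE 0.14, adjusted p = 8.82e-06) while Gadd45a, also a p53 target, was higher (1.08, SE 0.11, adjusted p = 2.90e-07), and 4 of 26 p53 targets were higher with 5 lower (list adjusted p = 0.816). The lysosomal galactosidase gene Glb1 was lower (-1.23, SE 0.10, adjusted p = 1.45e-08) and so was Ccnd1, which encodes cyclin D1 (-1.07, SE 0.09, adjusted p = 8.51e-09). Within transgenic islets Cdkn1a differed by -1.17, Gadd45a by 1.14, Glb1 by -1.25 and Ccnd1 by -1.25.

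Class I antigen presentation was higher in NOD islets. Of 20 measured genes 12 were higher, 1 was lower and 7 did not pass (13 higher and 1 lower when adjusted over the list alone), with a median log2 difference of 0.39 (camera, adjusted p = 0.00671, and 0.733 with an estimated correlation). Within transgenic islets 6 were higher with a median of 0.31 (adjusted p = 0.00699, and 0.690 with an estimated correlation). The immunoproteasome gene Psmb8 was higher by 0.59 (SE 0.10, adjusted p = 1.63e-04), and by 0.70 within transgenic islets. H2-Q4 was higher by 0.81 (SE 0.09, adjusted p = 1.07e-06) and by 0.69 within transgenic islets, with reads that class I paralogs can share. The peptide-trimming gene Erap1 was lower (-0.60, SE 0.09, adjusted p = 3.62e-05) but did not pass within transgenic islets (-0.35, adjusted p = 0.0874). The interferon-stimulated list was higher in non-transgenic NOD islets, with 12 of 30 genes higher, 0 lower and 18 not passing (15 when adjusted over the list alone, median 0.66, adjusted p = 0.00280, and 0.826 with an estimated correlation), among them Gbp2 (1.09, SE 0.23, adjusted p = 0.00210) and Ifi35 (0.85, SE 0.16, adjusted p = 6.91e-04). That list call ended without NOD replicate 2 (median 0.36, adjusted p = 0.0933) and with the islet number as a covariate (0.210). In transgenic islets the interferon-stimulated list did not pass (median 0.11, adjusted p = 0.737), and its interaction was -0.54 (adjusted p = 1.50e-04, and 0.659 with an estimated correlation).

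Endothelial genes were higher in non-transgenic NOD islets. Of 13 endothelial genes 11 were higher, 0 lower and 2 did not pass (11 when adjusted over the list alone), with a median log2 difference of 0.66 (camera, adjusted p = 4.25e-06, and 0.676 with an estimated correlation). In the same comparison the acinar list was lower (median -4.46, adjusted p = 1.62e-05, and 0.826 with an estimated correlation), and the mitochondrially encoded list (0.48, 0.0184, and 0.826) and the immediate early and dissociation stress list (0.67, 0.0361, and 0.780) were higher. Plvap, which encodes the diaphragm protein of fenestrated endothelium, had 147 ± 8.75 CPM in B10 and 311 ± 71.3 in NOD (n = 3, log2 difference 1.09, SE 0.14, adjusted p = 7.69e-06). Cdh5 was higher by 0.98 (SE 0.13, adjusted p = 1.08e-05) and Tek by 0.66 (SE 0.12, adjusted p = 3.16e-04). In transgenic islets the endothelial list did not pass (median 0.02, adjusted p = 0.837), and the interaction was -0.69 (adjusted p = 7.09e-14, and 0.395 with an estimated correlation). The matrix gene Sparc was higher with and without the transgene, by 1.02 averaged (SE 0.10, adjusted p = 1.30e-07) and by 0.83 within transgenic islets (SE 0.14, adjusted p = 3.60e-04). The stellate cell and fibroblast list was higher in non-transgenic islets (5 of 16, median 0.51, adjusted p = 0.0184, and 0.826 with an estimated correlation), a call lost without B10 replicate 3 or NOD replicate 2 (adjusted p up to 0.0933) and reversed in direction with the islet number as a covariate (median -0.11, adjusted p = 0.979).

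With insHEL 1052 genes differed in B10 islets (628 higher and 424 lower). There the description numbers divide the 2 groups, so that transgene and a possible batch cannot be told apart. In NOD islets 1084 genes differed (596 higher and 488 lower). Both sets shared 207 genes that rose (24.4 expected by chance) and 98 that fell (13.5 expected), and 5 moved in opposite directions. Of the genes called in B10, 87.0% had the same sign in NOD. Across all genes, which are not independent replicates, the log2 changes in the 2 strains, computed from separate libraries, had a Pearson r of 0.37. The count in B10 was 451, 541, 428 and 473 without B10 replicate 1, 2, 3 and B10_insHEL replicate 3, 578 with the islet number and 232 with the acinar score as a covariate, and 646 with only the groups compared. The count in NOD was 362, 396, 107 and 171 without NOD replicate 2, NOD replicate 3, NOD_insHEL replicate 1 and NOD_insHEL replicate 2. After thinning the counts were 150 in B10 (117 higher and 33 lower) and 32 in NOD (30 higher and 2 lower). Without both B10_insHEL replicate 2 and NOD_insHEL replicate 3 they were 1754 and 1964. In NOD the balance of directions also moved to 559 higher and 562 lower with the stricter filter. Without NOD replicate 1 it was 404 higher and 440 lower.

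H2-K1 (ENSMUSG00000061232, chromosome 17, 33996017 to 34000347), a class I heavy chain gene, rose in both strains. It had 174 ± 7.49 CPM in B10 and 4633 ± 946 in B10_insHEL (n = 3 each, log2 change 4.74, SE 0.16, adjusted p = 2.58e-14), and 265 ± 33.3 CPM in NOD and 4772 ± 289 in NOD_insHEL (n = 3 each, 4.17, SE 0.15, adjusted p = 1.97e-13). The other 19 class I genes had median log2 changes of -0.18 in B10 and -0.09 in NOD. Of these Tapbpl rose in B10 (0.54, SE 0.14, adjusted p = 0.0264), H2-Q4 fell in NOD (-0.61, SE 0.13, adjusted p = 0.0103), and the others did not pass in either strain. Of the neighbours, 0 of 76 tested genes within 1 Mb of H2-K1 changed in the same direction in both. The insHEL construct has no entry in the file, so that any of its reads counted on H2-K1 cannot be separated from those of the gene, and its level is uncertain.

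**Figure D3:**
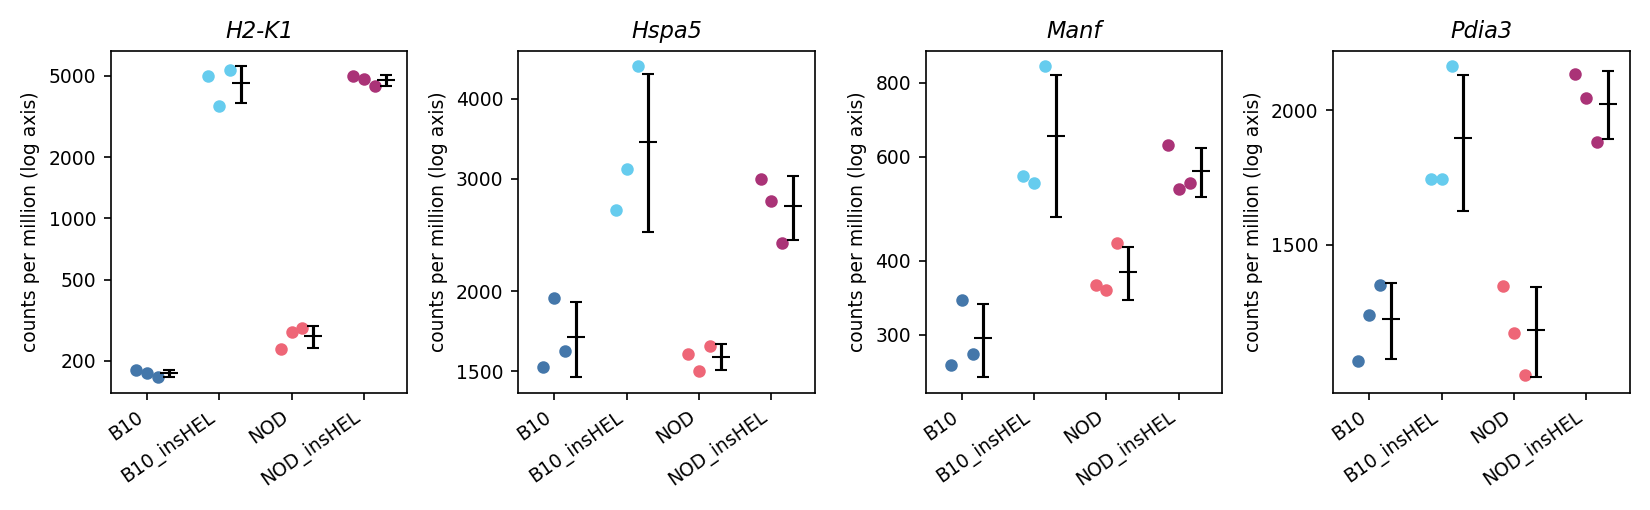
TMM-scaled CPM of H2-K1, Hspa5, Manf and Pdia3 in each library on a log axis, points being libraries and bars the mean ± SD of 3. H2-K1 lies between 166 and 291 CPM in the 6 libraries without insHEL and between 3555 and 5327 in the 6 with it.

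Chaperones and other genes of the unfolded protein response rose with insHEL in both strains. In B10 islets 22 of 30 rose, 0 fell and 8 did not pass (25 rose when adjusted over the list alone), with a median log2 change of 0.65 (camera, adjusted p = 1.48e-25, and 0.226 with an estimated correlation). In NOD islets 14 of 30 rose, 0 fell and 16 did not pass (20 when adjusted over the list alone), with a median of 0.45 (adjusted p = 3.95e-14, and 0.380 with an estimated correlation). All 30 lay above 0 in each strain. Hspa5 (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), which encodes the chaperone BiP, went from 1696 ± 228 to 3426 ± 949 CPM in B10 (n = 3 each, log2 change 1.01, SE 0.16, adjusted p = 8.32e-04) and from 1581 ± 71.7 to 2716 ± 313 in NOD (n = 3 each, 0.78, SE 0.16, adjusted p = 0.00848). Without NOD_insHEL replicate 1 the call in NOD ended (adjusted p = 0.0585). Manf, a secreted stress-response factor, rose by 1.14 in B10 (SE 0.16, adjusted p = 4.07e-04). In NOD Manf rose by 0.57 (SE 0.15, adjusted p = 0.0340), a call lost without NOD replicate 1, 2 or 3 or NOD_insHEL replicate 1 or 2 (adjusted p up to 0.157). Disulfide isomerase Pdia3 rose from 1249 ± 120 to 2028 ± 148 CPM in NOD (n = 3 each, 0.70, SE 0.12, adjusted p = 0.00432) and by 0.56 in B10. With the acinar score as a covariate the calls of Hspa5 and Manf in B10 were lost, with log2 changes of 0.79 and 0.80 (adjusted p = 0.0874 and 0.0599). The interaction did not pass for Hspa5 (-0.23, adjusted p = 0.704) or Manf (-0.57, adjusted p = 0.309), while the list had an interaction median of -0.22 (adjusted p = 0.0216, and 0.705 with an estimated correlation). The averaged strain difference did not pass for either (Hspa5 -0.22, adjusted p = 0.136, and Manf 0.09, adjusted p = 0.575). The list was lower in NOD by a median of -0.19 averaged (adjusted p = 0.0400, and 0.895 with an estimated correlation) and of -0.33 within transgenic islets (0.00154, and 0.926), and the ERAD gene Sel1l was lower in NOD (-1.001, SE 0.11, adjusted p = 1.07e-06, and -1.004 within transgenic islets, adjusted p = 1.66e-04).

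**Figure D4:**
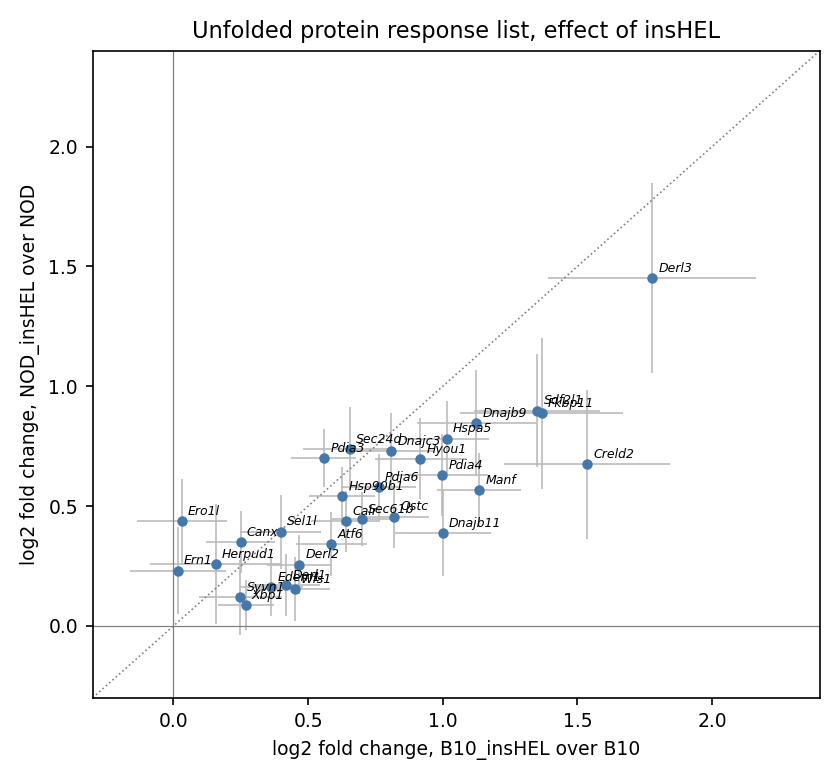
Log2 change of the 30 measured genes of the unfolded protein response list, B10_insHEL over B10 on the x axis and NOD_insHEL over NOD on the y axis, bars giving the SE and the dotted line equality. All 30 lie above 0 in each strain, with medians of 0.65 and 0.45.

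In B10 islets Aldh1a3, Slc2a2 and Mlph also differed with the transgene, in a comparison whose 2 groups the description numbers divide. Aldh1a3 (ENSMUSG00000015134, chromosome 7, 66390890 to 66427517), a retinaldehyde dehydrogenase, rose from 29.5 ± 1.78 to 215 ± 71.7 CPM (n = 3 each, log2 change 2.86, SE 0.39, adjusted p = 0.00423), against 1.61 ± 0.937 CPM in NOD and 4.72 ± 4.27 in NOD_insHEL. Its strain difference within transgenic islets was -5.18 (SE 0.49, adjusted p = 1.63e-04). The glucose transporter gene Slc2a2 fell from 747 ± 83.7 to 422 ± 126 CPM in B10 (n = 3 each, -0.83, SE 0.16, adjusted p = 0.00366) and was 1.03 higher in NOD_insHEL than in B10_insHEL (SE 0.16, adjusted p = 1.50e-04). Mlph, which encodes melanophilin, fell from 14.9 ± 2.65 to 1.45 ± 0.229 CPM (n = 3 each, -3.35, SE 0.23, adjusted p = 2.32e-08). The lysosomal channel gene Mcoln3 fell (-2.59, SE 0.30, adjusted p = 4.73e-05), and so did the quinone reductase gene Nqo1 (-1.52, SE 0.24, adjusted p = 7.35e-04). Thbs4, with 0 counts in B10, was at least 19.5-fold higher. Ins1 rose by 0.54 (SE 0.14, adjusted p = 0.0264), a call lost without B10 replicate 1, 2 or 3 or B10_insHEL replicate 1 or 3 (adjusted p up to 0.114) and with the acinar score as a covariate (0.03, adjusted p = 0.977). The acinar list was lower with the transgene in B10, with a median of -2.15 (adjusted p = 1.61e-10, and 0.788 with an estimated correlation), with 1 of 27 genes passing, and its median was -6.38 without B10_insHEL replicate 2. Of the 20 genes named for B10, 16 kept their call without any 1 library. Calls were lost without B10 replicate 1 (4), B10 replicate 3 (3), B10_insHEL replicate 1 (2) and B10_insHEL replicate 3 (4).

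In NOD islets the transgene went with lower endothelial transcripts. Of 13 endothelial genes 9 fell, 0 rose and 4 did not pass (13 fell when adjusted over the list alone), with a median log2 change of -0.56 (camera, adjusted p = 2.87e-11, and 0.333 with an estimated correlation). Also lower in this comparison were the duct list (median -0.38, adjusted p = 0.00414, and 0.333 with an estimated correlation), the acinar list (-1.45, 0.0115, and 0.824), the mitochondrially encoded list (-0.32, 0.0115, and 0.597), the class II list (-0.61, 0.00449, and 0.597) and the interferon-stimulated list (-0.47, 1.11e-04, and 0.597). Tek, an angiopoietin receptor gene, went from 54.8 ± 6.58 to 35.2 ± 2.60 CPM (n = 3 each, -0.63, SE 0.12, adjusted p = 0.00759, and 0.0557 without NOD_insHEL replicate 1). In B10 islets the endothelial list did not pass (median 0.15, adjusted p = 0.333), and neither did it for strain in transgenic islets. The higher endothelial list in NOD than in B10, its fall here and its interaction all use the same 3 NOD libraries. They are therefore not independent results. The interferon-stimulated and mitochondrially encoded lists were called in the same 3 comparisons and share this limit. Spp1, which encodes osteopontin, fell from 109 ± 32.96 to 18.9 ± 7.65 CPM (n = 3 each, -2.42, SE 0.30, adjusted p = 0.00432). Siglech, a plasmacytoid dendritic cell gene, fell from 4.81 ± 0.581 to 0.697 ± 0.618 CPM (n = 3 each, -3.34, SE 0.47, adjusted p = 0.00135). The prohormone convertase gene Pcsk1 rose from 414 ± 43.7 to 690 ± 85.2 CPM (n = 3 each, 0.74, SE 0.11, adjusted p = 0.00220). The proliferation list was higher (3 of 24 rose, 21 did not pass, median 0.68, adjusted p = 4.94e-05, and 0.598 with an estimated correlation). Of the 20 genes named for NOD only H2-K1, Siglech and Tmem212 kept their call without any 1 library. Calls were lost without NOD replicate 1 (8), NOD replicate 2 (12), NOD replicate 3 (12), NOD_insHEL replicate 1 (17), NOD_insHEL replicate 2 (15) and NOD_insHEL replicate 3 (3), and that last library is the shallowest.

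The transgene effect differed between the strains for 9 genes, 7 with a higher and 2 with a lower change in NOD (1873 at an unadjusted p under 0.05, and 105 adjusted by DESeq2). The B10 libraries enter each of these, so that a possible batch cannot be told apart from the transgene effect in B10. Dpp4, which encodes dipeptidyl peptidase 4, fell from 65.6 ± 10.3 to 25.5 ± 2.38 CPM with the transgene in B10 and went from 92.6 ± 11.2 to 126 ± 17.9 in NOD (n = 3 each, interaction 1.81, SE 0.19, adjusted p = 5.54e-05). Mlph went from 27.9 ± 0.739 to 19.9 ± 5.06 CPM in NOD, against the near loss in B10 (interaction 2.81, SE 0.30, adjusted p = 5.54e-05). Both calls remained when each of the 12 libraries was left out. Chl1, a neural adhesion gene, had an interaction of 1.87 (SE 0.30, adjusted p = 0.0309), which was lost without B10 replicate 1 or 3, B10_insHEL replicate 3, NOD replicate 2 or 3, or NOD_insHEL replicate 1 or 3 (adjusted p up to 0.116). The number of genes was 2 to 5 without B10 replicate 1, 2 or 3, B10_insHEL replicate 3, NOD replicate 2 or 3, or NOD_insHEL replicate 1 or 2, it was 20 without NOD replicate 1, and it was 162 without B10_insHEL replicate 2. The balance of directions moved too: there were 161 genes (89 with a higher and 72 with a lower change in NOD) without a filter on low counts, 51 (24 and 27) with the acinar score as a covariate, 105 (62 and 43) by DESeq2 and 283 (173 and 110) without both B10_insHEL replicate 2 and NOD_insHEL replicate 3. There were 5 without robust dispersions, 4 with the islet number as a covariate and 1 after thinning.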

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

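The tests of the endothelial pattern were chosen after the result was seen, while the interaction tests were chosen before the data were examined.

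The results in this part are those for which the transgene effect in NOD minus that in B10 passed the interaction test. All of them use the B10 libraries, so that a possible batch cannot be told apart from the transgene effect in B10. Among genes, Dpp4 differed by 1.81 (adjusted p = 5.54e-05), falling in B10 (-1.36), with a change of 0.46 in NOD. Mlph differed by 2.81 (adjusted p = 5.54e-05, -3.35 in B10 and -0.54 in NOD). Both passed without each of the 12 libraries in turn. Chl1 differed by 1.87 (-0.90 and 0.97), Ank2 by 0.96 (-1.10 and -0.14), Fmo1 by 1.04 (-0.73 and 0.31) and Podxl by -1.03 (0.42 and -0.60), each with an adjusted p of 0.0309. Pla2g2d differed by 1.90 (-0.99 and 0.91), Slitrk6 by 0.88 (-0.32 and 0.55) and Flt1 by -0.82 (0.37 and -0.45), each with an adjusted p of 0.0490. Chl1, Ank2, Fmo1 and Flt1 lost their calls without NOD replicate 3, with adjusted p of 0.116, 0.128, 0.128 and 0.190. Without B10 replicate 3, NOD replicate 2 or NOD replicate 3 the count of genes was 2, so that the 7 genes other than Dpp4 and Mlph lost their calls. Ank2 was also lost without B10 replicate 1 or 2, B10_insHEL replicate 3, or NOD_insHEL replicate 2 or 3, Fmo1 without B10 replicate 1, B10_insHEL replicate 1 or 3, or NOD_insHEL replicate 1, 2 or 3, and Flt1 without B10 replicate 1 or 2, B10_insHEL replicate 1 or 3, or NOD_insHEL replicate 1, 2 or 3.

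Among gene lists, 9 passed the interaction test at the preset correlation and 0 of 27 passed with an estimated correlation. The median difference was 0.18 for the beta cell list (adjusted p = 0.0446, and 0.495 with an estimated correlation), 0.61 for the acinar list (7.73e-04, and 0.659), -0.69 for the endothelial list (7.09e-14, and 0.395), -0.88 for the red blood cell list (0.0431, and 0.495), -0.54 for the interferon-stimulated list (1.50e-04, and 0.659), -0.22 for the unfolded protein response list (0.0216, and 0.705), 0.23 for the double-strand break repair list (0.0431, and 0.495), -0.52 for the mitochondrially encoded list (5.28e-05, and 0.495) and -0.49 for the immediate early list (0.0216, and 0.495). The beta cell call ended without B10 replicate 1, B10_insHEL replicate 2, NOD replicate 2 or 3, or NOD_insHEL replicate 2 or 3 (adjusted p up to 0.222). The red blood cell call ended without B10 replicate 1, B10_insHEL replicate 1 or 2, NOD replicate 2, or NOD_insHEL replicate 1 or 2 (up to 0.144). The double-strand break repair call ended without B10 replicate 2, B10_insHEL replicate 2 or 3, NOD replicate 3 or NOD_insHEL replicate 1 (up to 0.130). The unfolded protein response call ended without B10 replicate 1 or 3, B10_insHEL replicate 3 or NOD_insHEL replicate 3 (up to 0.455), and the immediate early call without B10_insHEL replicate 2, NOD replicate 2 or NOD_insHEL replicate 2 (up to 0.157). The acinar median was 4.74 without B10_insHEL replicate 2, 0.07 without B10_insHEL replicate 1, 0.05 without B10_insHEL replicate 3, 0.40 without NOD replicate 1 and 0.14 without NOD_insHEL replicate 1. The interferon-stimulated median was -0.28 without NOD replicate 2.

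The endothelial list fell with the transgene in NOD islets (median log2 change -0.56) at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.333), and not in B10 islets (0.15). A lower share of all non-endocrine cells alike is argued against for these 6 libraries only. The stellate and macrophage genes lay 0.550 above the endothelial genes in the median (34 genes, two-sided permutation p = 0.0015). That permutation shuffles genes, which are not independent, and does not measure the spread between mice. Without each library in turn the stellate median lay between -0.208 and 0.0908 and the macrophage median between -0.155 and 0.120. The duct list (median -0.38, adjusted p = 0.00414, and 0.333 with an estimated correlation) and the acinar list (-1.45, 0.0115, and 0.824) were lower too at the preset correlation. The adipocyte list, of which only Fabp4 and Lpl were measured, did not pass at either (2 genes, 1 of which fell, median -0.54, 0.0580, and 0.380). A joint loss of some of these cell types was not tested and stays open. The mitochondrially encoded list fell in NOD as well (median -0.32, adjusted p = 0.0115, and 0.597 with an estimated correlation) and not in B10 (0.19, 0.151). A single library is argued against as well, since the median stayed between -0.653 and -0.398 without each of the 6 libraries. All 13 of 13 measured endothelial genes lay below 0, which fewer endothelial cells per islet and a lower expression in those cells would give alike, so that this count supports neither over the other and both stay open. Only NOD and NOD_insHEL enter the fall, so that the description numbers do not divide its 2 groups. The NOD libraries also enter the endothelial difference between NOD and B10 and the interaction. The fall is therefore not independent of those results.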

How the results depend on the processing

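Leaving out both B10_insHEL replicate 2 and NOD_insHEL replicate 3, and thinning all libraries to the shallowest, were chosen after the results were seen, and the other alternatives before.

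Of 429 calls of named genes, 425 remained with RLE scaling, 424 with TMM computed without acinar, red blood cell and mitochondrially encoded genes, 418 without a filter, 421 without robust dispersions and 411 with the replicate number as a block. DESeq2 kept 400 of 406, the stricter filter 334 of 339 and fits of only the groups compared 259 of 290. The islet number covariate kept 373 of 429 and the acinar score covariate 273, and thinning to equal depth kept 134 of 361. These tallies pool the 6 comparisons, except that fits of only the groups compared leave out the averaged strain difference and the interaction. A gene with no adjusted p in an alternative, for example one removed by its filter, is not in that denominator. Its call is thus counted neither as kept nor as lost. Of 40 list calls all 40 remained with RLE, with the other TMM, without a filter, without robust dispersions and with the block, 37 with the stricter filter, 31 with the islet number, 29 with the acinar score, 29 after thinning, 15 with fry and 0 with an estimated correlation. Replicate numbers did not pair the mice: of 18 pairs with the same number 0 had a correlation over 0.1 (r from -0.0950 to 0.0803), and the block gave 1857, 4263, 5023, 1032, 961 and 8 genes for strain in transgenic islets, strain in non-transgenic islets, strain averaged, the transgene in B10, the transgene in NOD and the interaction.

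Counts of genes that moved by over 1.5-fold follow, and the cause was not tested unless fewer libraries or reads give it. For strain in transgenic islets the count was 1197 with only the groups compared and 260 after thinning (1344 to 1978 without 1 library). For strain in non-transgenic islets it was 2688 with the islet number, 1111 with the acinar score and 692 after thinning (2868 to 4021 without 1 library, the lowest without NOD replicate 3). Averaged, it was 2090 with the acinar score, 1079 after thinning and 1850 within description numbers 1 to 29 (4301 to 5245 without 1 library). For the transgene in B10 it was 578 with the islet number, 232 with the acinar score, 646 with only the groups compared, 1754 without both libraries that stand apart and 150 after thinning (428 to 1566 without 1 library, moved by leaving out B10 replicate 1, 2 or 3 or B10_insHEL replicate 3). For the transgene in NOD it was 1964 without both libraries and 32 after thinning (107 to 1348 without 1 library, moved by leaving out NOD replicate 2 or 3 or NOD_insHEL replicate 1 or 2). The interaction gave 161 genes without a filter, 5 without robust dispersions, 4 with the islet number, 51 with the acinar score, 283 without both libraries, 1 after thinning and 105 with DESeq2 (2 to 162 without 1 library).

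Several results reversed. With the acinar score as a covariate the acinar list changed direction for strain in non-transgenic islets (adjusted p = 0.00286), strain averaged (0.105), the transgene in B10 (0.0643) and the interaction (0.00786), by construction since the score is the mean of that list. The nuclear-encoded respiratory chain list reversed for strain in non-transgenic islets (0.00671) and the transgene in B10 (0.498), as did the log2 differences of Reg3g (0.15), Prss2 (0.66), Rbpjl (2.64), Cuzd1 (0.0528), Ctrc (0.31) and Cox4i1 (-0.0192) in non-transgenic islets and of Prss2 (0.54) and Cuzd1 (0.57) averaged. With the islet number the stellate list reversed for strain in non-transgenic islets (adjusted p = 0.979), the transgene in B10 (0.0130) and the interaction (0.0294). After thinning the red blood cell list reversed for the transgene in B10 (0.643) and the interaction (0.602), and so did the strain differences in non-transgenic islets of Xrcc5 (0.19), Gsr (0.0216) and Cox5b (-0.14). Without B10_insHEL replicate 2 the acinar list reversed for strain in transgenic islets (0.0460, over a range of 8.00e-05 to 0.202 without 1 library). Prss2, Rbpjl, Cuzd1 and Ctrc are members of the acinar list, so that the score used as a covariate contains them. The cause was not tested for the other reversals. Thinning kept 134 of 361 named calls, so that depth limits the number of genes called.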

Other observations

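The tests of H2-K1 and those of the integrated stress response list with the acinar score and the description numbers were chosen after the results were seen, while the matched random lists and the splits of the libraries were chosen before.

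In NOD islets the transgene went with lower Spp1 (-2.42) and with a lower duct list (3 of 12 fell, 9 did not pass, median log2 change -0.38, adjusted p = 0.00414, and 0.333 with an estimated correlation), with a median of -0.17 without NOD_insHEL replicate 2. The class II presentation list was lower (2 of 10 fell, 8 did not pass, 4 fell when adjusted over the list alone, median -0.61, adjusted p = 0.00449, and 0.597 with an estimated correlation), a call lost without NOD replicate 3 or NOD_insHEL replicate 1 (adjusted p up to 0.0818). The interferon-stimulated list was lower (3 of 30 fell, 27 did not pass, 6 fell when adjusted over the list alone, median -0.47, adjusted p = 1.11e-04, and 0.597 with an estimated correlation), with a median of -0.25 without NOD replicate 2. The mitochondrially encoded list had a median of -0.32 (adjusted p = 0.0115, and 0.597 with an estimated correlation), with 0 of 7 lower, 7 not passing and 2 lower when adjusted over the list alone, and the call was lost without NOD replicate 3 or NOD_insHEL replicate 1 (adjusted p up to 0.0818). The acinar list had a median of -1.45 in NOD (adjusted p = 0.0115, and 0.824 with an estimated correlation).

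In B10 islets the transgene went with lower Fabp4 and Lpl (-0.96), the only measured genes of the adipocyte list (2 of 2 fell, median -0.80, adjusted p = 0.00216, and 0.200 with an estimated correlation). Adipoq, Plin1, Lep, Cfd, Retn and Cidec of that list were not measurable, so that a change in adipocytes is not shown. The nuclear-encoded respiratory chain list was higher (2 of 28 rose, 26 did not pass, 7 rose when adjusted over the list alone, median 0.23, adjusted p = 2.59e-05, and 0.794 with an estimated correlation). Its median was 0.35 without B10_insHEL replicate 2 and 0.13 without B10_insHEL replicate 3, and it reversed in direction with the acinar score as a covariate (median -0.05, adjusted p = 0.498). The proliferation list was higher in B10 (2 of 24 rose, 22 did not pass, median 0.46, adjusted p = 5.22e-04, and 0.788 with an estimated correlation), a call lost without B10_insHEL replicate 1 (0.0934). The red blood cell list had a median of 0.69 (adjusted p = 0.0354, and 0.763 with an estimated correlation), lost without B10 replicate 1, B10_insHEL replicate 1 or B10_insHEL replicate 2 (adjusted p up to 0.161) and reversed in direction after thinning to equal depth (median -1.63, adjusted p = 0.643), and its globin paralogs can share reads.

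Between strains, averaged over the transgene, endothelial genes (8 of 13 higher and 1 lower, median 0.37, adjusted p = 0.0304), stellate genes (6 of 16 higher, median 0.39, adjusted p = 0.0347) and the unfolded protein response list (1 of 30 higher and 8 lower, median -0.19, adjusted p = 0.0400) passed at the preset correlation and not with an estimated one (adjusted p = 0.895 each). The endothelial call ended without B10 replicate 2, NOD replicate 2 or NOD_insHEL replicate 2 (adjusted p up to 0.0754), the stellate call without B10 replicate 3, B10_insHEL replicate 1 or 3, NOD replicate 2 or 3, or NOD_insHEL replicate 2 (up to 0.117), and the unfolded protein response call without B10 replicate 2, B10_insHEL replicate 3, NOD replicate 2 or 3, or NOD_insHEL replicate 2 or 3 (up to 0.225). The unfolded protein response list was also lower in NOD_insHEL than in B10_insHEL (5 of 30, median -0.33, adjusted p = 0.00154, and 0.926 with an estimated correlation), with a median of -0.17 and no call without B10_insHEL replicate 3 (0.163). In non-transgenic islets the lists of class I genes (9 of 20 higher and 1 lower, adjusted p = 0.0184, and 0.676 with an estimated correlation), mitochondrially encoded genes (5 of 7 higher, median 0.48, adjusted p = 0.0184, and 0.826) and immediate early genes (6 of 21 higher, median 0.67, adjusted p = 0.0361, and 0.780) were higher in NOD. The mitochondrially encoded call ended without B10 replicate 2 (0.0537), and the immediate early call without B10 replicate 1 or NOD replicate 2 (up to 0.124, with a median of 0.34). The lists not called for the averaged strain difference and not mentioned elsewhere were alpha cell (0 higher and 4 lower of 13, adjusted p = 0.121), delta and PP cell (3 and 1 of 8, 0.816), Schwann cell (4 and 2 of 8, 0.511), macrophage (5 and 1 of 18, 0.293), senescence (3 and 5 of 11, 0.423), apoptosis regulators (1 and 1 of 20, 0.999), antioxidant response (3 and 5 of 22, 0.816) and hypoxia and glycolysis (3 and 4 of 20, 0.755). Xist had 1 to 11 counts per library, beside the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty in all 12.

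H2-K1 was higher in each of the 6 insHEL libraries, the lowest of which exceeded the highest library without the transgene 12.2-fold. An induction of class I presentation is argued against, since the other 19 class I genes had median changes of -0.178 in B10 and -0.0942 in NOD and 0 of them rose by over 1 on the log2 scale, though Tapbpl passed in B10 (0.54). A different MHC haplotype is argued against, since 0% of the 76 tested genes within 1 Mb changed in the same direction in both strains. Reads of the insHEL construct counted on H2-K1 remain a candidate explanation: the sequence of the construct is not among the files, and reads could not be examined.

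The integrated stress response list was lower in NOD islets (median -0.67) at the preset correlation, a call lost with an estimated correlation (adjusted p = 0.733 averaged and 0.690 within transgenic islets). Acinar cells as the cause are argued against, since the median was -0.635 with the acinar score as a covariate (adjusted p = 1.50e-09). Within groups that score varied mainly through B10_insHEL replicate 2 (4.91, against 1.505 and 1.17 in replicates 1 and 3), so that this adjustment rests largely on 1 library. In transgenic islets the median stayed between -0.737 and -0.461 without each library in turn, B10_insHEL replicate 2 included. A batch marked by the description numbers is argued against, since within the libraries numbered 1 to 29 the median was -0.595 (adjusted p = 5.13e-09). A general loss of reads from NOD alleles is argued against, since 0% of 10000 random lists matched on expression had a median as low, the lowest being -0.364. A loss of reads specific to these genes was not tested, and a lower activity of the pathway in NOD islets stays among the open explanations as untested.

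Splits of the same libraries into other groups were fitted for each count of genes. With 10 splits of 6 libraries, 1 of them the real one, the splits are too few for a share under 0.05: the real count and the highest other were 1850 and 0 for strain in transgenic islets, 4353 and 0 for strain in non-transgenic islets, 1052 and 6 for the transgene in B10, and 1084 and 0 for the transgene in NOD. For the averaged strain difference, 1 of 100 splits, the real one, gave 5107 genes, and the highest other gave 2029. The real split thus had a share under 0.05, but splits that mix the strains add the strain difference to the spread. Their counts therefore do not show how many genes chance would give. For the interaction, 4 of 100 splits gave at least the real count of 9, and the highest other gave 2337. These splits do not decide whether chance can be excluded, since those that mix the transgene labels within a strain add the transgene effect to the spread. The highest split exchanges the transgene labels of all B10 libraries, so that by construction it measures the sum of the transgene effects in both strains. That is the known structure of these samples, and no other structure was tested.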
